A study of Oryza sativa with 2 samples.

How the data were processed

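Cleaved RNA was measured in shoots of the indica rice cultivar Zhong Jiazao-17, an early maturing cultivar known, per the labels, for low cadmium in the grain. Per the labels, seedlings grew in Hoagland's nutrient solution at pH 5.5, 80% relative humidity and 30 °C by day and 28 °C by night. From the 1-leaf stage they received 0 or 100 µM cadmium chloride for 12 days. Per the labels, each treatment was run in triplicate, but 1 degradome library per treatment is described, and whether it pooled the 3 cultures is not given in the sources used here.

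Degradome sequencing reads the 5′ ends of uncapped RNA fragments. A microRNA (miRNA) guides Argonaute to cut a matching transcript opposite positions 10 and 11 of the miRNA, which leaves a 3′ fragment with a 5′ monophosphate. Per the labels' protocols, total RNA with an integrity number above 7.0 was used, about 20 µg of it per library. About 150 ng of poly(A)+ RNA was annealed to biotinylated random primers, and the 5′ adaptor was ligated to fragments carrying a 5′ monophosphate. After reverse transcription and PCR, the first 36 nt of the inserts were read single-end on an Illumina HiSeq sequencer. The adapter trimming, alignment program, target caller and genome release are not given in the sources used here. Random priming and PCR without molecular identifiers mean that reads are not independent molecules, so every interval and floor given here covers counting error only.

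The deposited table lists pairs of a small RNA and a predicted target transcript. Per the file headers, each pair carries an alignment score, where 0 is a perfect match and mismatches add to the score, and a cleavage position counted within the transcript. For each library the deposited table gives the raw read count at the position, a normalized count, a depth-scaled value (normalized reads per 1e+09 library reads), a category and a site p-value. Per the file headers, the authors also gave p-values from a chi-square test and from Fisher's exact test, and a log2 ratio of cadmium over control. Normalized counts never exceeded raw counts. They were fractions of the raw count where reads matched several transcripts, so the deposited normalized count divides a read among the transcripts it matches. The deposited log2 ratio equalled the log2 ratio of the depth-scaled values in each of the 740 pairs with reads in both libraries. Categories 0 to 4 are the usual degradome classes, which rank a site by how far its reads stand above the other reads of its transcript. Category 0 is the single highest position of the transcript and category 4 a position with 1 read. Library columns were assigned to treatments from the letters in their names. Pairs without degradome reads end after 11 of the 28 columns, so the range of each measured column was checked by script on the full lines only.

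Library depth was taken from the constant ratio of the depth-scaled value to the normalized count, which gave 14047778 reads for cadmium and 12390779 for control. Several small RNAs of a family report the same reads, so the unit was the distinct site, a transcript and a position within it. Ratios of cadmium to control used reads per library read. Intervals of ratios are exact 95% binomial intervals on the 2 counts, scaled by depth, intervals of shares are exact Clopper-Pearson intervals, and intervals of counts are exact Poisson intervals. A count of 0 was treated as up to 3 counts in the library, and folds against 0 are set against that floor. Such folds leave out the counting error of the higher count, so the lower end of the exact interval is given beside them. Sites with at least 10 reads in the higher library are called abundant. With 1 library per treatment no difference has a replicate check, and a 2-fold difference is a rule of size. The comparisons of the report use no p-value, except Fisher's exact test on reads beside the deposited p-values in the closing part. That test treats reads as independent and compares the 2 libraries only. Loci merge the isoforms of a gene and keep the highest site, and raw reads that match several genes count at each of them. Transcript identifiers and gene names are those of the deposited annotation, which names the best protein match, often from another species. The reference gene table in use matched 0 of the locus identifiers, so no chromosome coordinates are given, and positions are within transcripts.

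Lists, alternatives and the rule for named sites were chosen before the data were examined. The 28 miRNA family lists were miR156 with miR529 and miR535, miR159 with miR319, miR160, miR162, miR164, miR165 with miR166, miR167, miR168, miR169, miR170 with miR171, miR172, miR390, miR393, miR394, miR395, miR396, miR397, miR398, miR399, miR408, miR444, miR528, miR530, miR820, miR827, miR1425, miR1432 and miR2118 with miR2275, each with its textbook target class. The 16 target lists were matched on annotation words: metal transport, sulfur and thiol metabolism, redox enzymes, copper proteins, transporters, chaperones, transcription factors, auxin signalling, small RNA machinery, photosynthesis and chloroplast, ribosome and translation, protein kinases, F-box and ubiquitin, disease resistance, cell wall and lignin, and pentatricopeptide repeat proteins. A list with at least 3 abundant sites with reads in both libraries was given its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on abundance in 3 bins. Named sites were the most abundant site of the expected class per family, and the 10 largest differences in each direction among abundant sites of category 0 to 2 with reads in both libraries. The 5 highest sites per library and the 5 highest sites seen in that library only, with 1 site per transcript, completed the rule. Isoforms of a gene fill several of these places, so 54 entries came from 43 loci. Summed reads per family, the joint group of miR397, miR398, miR408 and miR528, the list of loci past 2-fold, the adjacent cleavage positions and the recalculation of the deposited p-values were added after the data were seen, as were further loci named beside their family.

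The alternatives covered category, site p-value, alignment score, unit, scaling, read minimum and pseudocount. In simulated libraries with the real depths and 539 sites, of which 113 were abundant with reads in both, 100% of the sites set 4-fold higher and 100% of those set 4-fold lower passed 2-fold. Of the unchanged sites scored, 6.0% passed 2-fold, and 92.0% of the counting intervals held the true ratio. The simulated reads were independent Poisson counts, without PCR duplication or reads shared between isoforms, so these shares are likely too favourable for the real libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Transcript levels and small RNA levels of these shoots were not analysed here.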

Results

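The study set a degradome library of cadmium-treated rice shoots against a library of untreated shoots to find which transcripts miRNAs cut under cadmium stress. The libraries held 14047778 (cadmium) and 12390779 (control) reads, 1 library per treatment, so no difference below has a replicate check. Reads at predicted cleavage sites were a small part of this. They came to 9403 normalized reads, or 0.0669% of the cadmium library, and 6743 normalized reads, or 0.0544% of the control library.

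Both libraries had reads at textbook targets of 20 of the 28 listed miRNA families, including auxin response factors (miR160), NF-YA subunits (miR169), APETALA2-like factors (miR172), scarecrow-like factors (miR171) and class III HD-ZIP factors (miR166). By normalized reads per transcript, the highest site in both libraries was the miR408 site at position 668 of LOC_Os08g37670, with 3148 reads in cadmium and 575 in control, followed in control by ARF22 with 537. By raw reads, which isoforms share, ARF18 (LOC_Os06g47150, 1163 reads), NFYA9 (LOC_Os03g48970, 979 reads) and AP2 (LOC_Os05g03040, 676 reads) had more in control. No site was recorded for miR168, which targets ARGONAUTE 1 transcripts. Of 8485 predicted pairs, 1235 (14.6%) had reads, from 225 of 544 small RNAs. These pairs made up 539 distinct sites on 479 transcripts of 315 loci. The cadmium library had reads at 359 sites and the control library at 389, and 209 sites had reads in both, 150 in cadmium only and 180 in control only. By locus, 115 had reads in both, 97 in cadmium only and 103 in control only. Of the 539 sites, 474 lay opposite position 10 of the miRNA.

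Most sites seen in 1 library lay at the limit of detection. Of the 330 such sites, 282 had 3 or fewer reads, and 6 had 10 or more. Those 6 sites, on 4 loci, were in cadmium only, and each belonged to miR397 or miR528. The median site had 3 reads in cadmium and 2 in control, so absence of most sites from a library was not distinguishable from low depth. No control-only site had over 7 reads. By normalized reads, the highest was the miR167 site of the histone chaperone gene HIRA (LOC_Os09g39420), with 7 reads. It was 2.65-fold higher in control against the floor, with an interval from 1.63. The next 4, each with 4 reads, did not differ from cadmium beyond counting error, since the interval of control over cadmium began at 0.748. They were in HO1 (LOC_Os06g40080), a heme oxygenase gene, in a SWR1-type helicase gene (LOC_Os12g38970), at position 784 of NAC021 (LOC_Os08g10080) and in LOC_Os01g64270, which has no annotation.

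Sites that were the highest position of their transcript recurred between treatments, and sites with a single read mostly did not. Category 0 held 111 of 359 sites in cadmium (30.9%, 95% interval 26.2 to 36.0) and 89 of 389 in control (22.9%, 18.8 to 27.4). Category 4 held 107 sites in cadmium (29.8%, 25.1 to 34.8) and 149 in control (38.3%, 33.4 to 43.3). Category 2 held 34.0% and 36.2% of the sites. Categories 1 and 3 held 14 and 5 sites in cadmium and 8 and 2 in control. The intervals of the 2 libraries overlapped for category 0 and for category 4, which does not show that the shares are equal. These intervals count isoforms that share reads as separate sites. With 1 site per locus the category 0 shares were 30.5% in cadmium and 22.6% in control. Of the category 0 sites, 90.1% of those in cadmium and 97.8% of those in control also had reads in the other library. For category 4 these shares were 24.3% and 24.8%.

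Reads at abundant sites differed in both directions between cadmium and control. Among 59 abundant loci, 55 had reads in both libraries. Of these, 14 were at least 2-fold higher in cadmium, 11 at least 2-fold lower, and 30 in between. The other 4 had reads in cadmium only. The 14 higher loci held 8 targets of miR397, miR398, miR408 or miR528, families whose textbook targets include many copper proteins, and of these 8 only SODCC2 and LAC7 are annotated as copper proteins. No locus of these families was among the 11 lower ones. The other 6 higher loci were NAC021 (LOC_Os12g41680), NAC100 (LOC_Os02g36880), MADS27, GRF1, SAP11 and the auxin receptor gene Os05g0150500. The 11 lower loci were NFYA9, NFYA3 (LOC_Os07g41720), SCL6 (LOC_Os04g46860), ARF8, ARF17, GRF3, SPL12, NAC100 (LOC_Os04g38720), DCL1, a remorin gene and a chlorophyll a-b binding protein gene. Of these, SCL6, NFYA9, SPL12 and ARF8 came inside 2-fold with the median of shared sites set to 0. That median counts isoforms separately, and the median over loci, 0.00, would leave these loci past 2-fold. Of the higher loci, LOC_Os08g04310, NAC021, Os05g0150500 and SAP11 came inside 2-fold when scaled by summed site reads. Over the 55 loci the median log2 ratio was 0.00 (quartiles -0.83 and 0.99). By distinct site, where isoforms count separately, 109 abundant sites had reads in both libraries, 22 were at least 2-fold higher and 26 at least 2-fold lower, with a median log2 ratio of -0.26 (quartiles -0.96 and 0.74). Setting that median to 0 gave 26 higher and 12 lower, and scaling by the summed site reads, a shift of 0.30 on the log2 scale, gave 18 and 39.

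**Figure D1:**
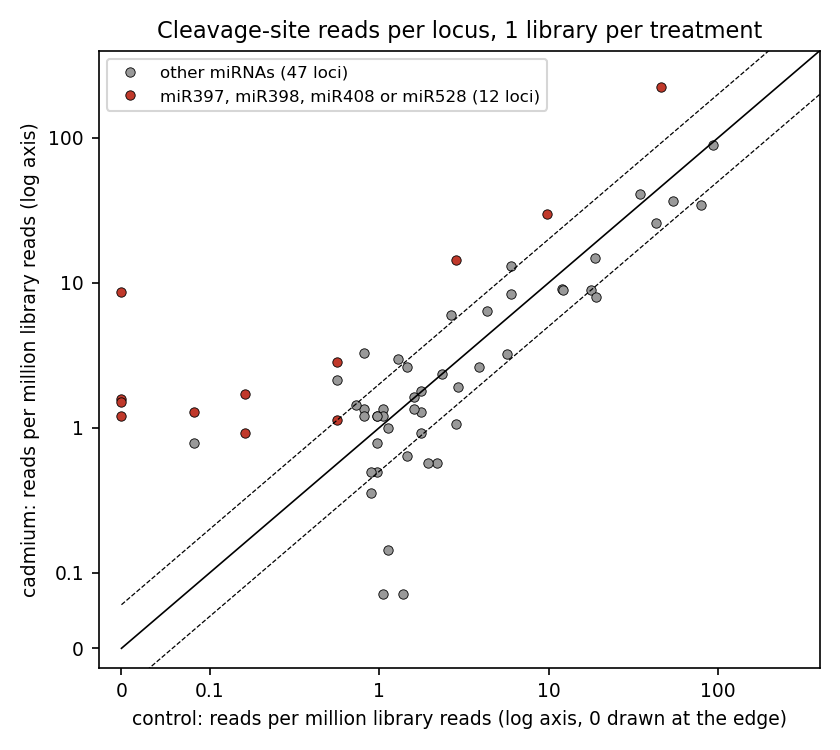
Depth-scaled reads at the highest cleavage site of each of 59 abundant loci, control on the horizontal and cadmium on the vertical log axis, with 0 drawn at the edge. The solid line marks equal values and the dashed lines 2-fold, and all 12 loci of miR397, miR398, miR408 and miR528 (red) lie above the 2-fold line or have no control reads.

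Transcripts cut by miR397, miR398, miR408 and miR528 had several times more cleavage reads in cadmium. Summed over their 35 sites on 22 loci, reads were 4101 in cadmium and 753 in control, 4.80-fold higher per library read (95% counting interval 4.44 to 5.20). All 12 of these loci with 10 or more reads had more reads in cadmium, of which 7 have weak alignment scores, above 3, and the other loci had fewer than 10 reads, several of them a single read. All other sites together were 1.28-fold lower (1.23 to 1.33). The families were grouped after their values were seen. Sites whose annotation names a copper protein held 265 of these reads in cadmium and 39 in control, a ratio of 5.99 (4.27 to 8.62). By family, the ratio was 15.7 (5.85 to 59.0) for miR397, 5.39 (3.79 to 7.85) for miR398, 4.84 (4.43 to 5.30) for miR408 and 4.18 (3.47 to 5.06) for miR528. Without the site of LOC_Os07g38290 the ratio of miR528 was 13.4 (7.96 to 24.4), a sum that includes LOC_Os03g03724 with score 4. With alignment scores at or below 3 the log2 ratio of miR528 was 1.62 in place of 2.06. For miR397 it was 3.14 in place of 3.97.

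Among the targets of these families, the miR398 site of SODCC2 (LOC_Os07g46990), a cytosolic copper/zinc superoxide dismutase, had 202 reads in cadmium and 35 in control, a log2 ratio of 2.35. The other miR398 locus, annotated as selenium-binding protein 1 (LOC_Os01g68770), had 24 and 2 reads, a ratio of 10.6 (2.63 to 92.4). Laccases, copper enzymes that polymerise lignin and the textbook targets of miR397, had 49 reads at 6 loci in cadmium and 4 in control, a ratio of 10.8 (3.96 to 41.2). LAC24 (LOC_Os12g15680) had 21 reads in cadmium and 0 in control, 6.17-fold higher against the floor, with an interval from 4.59. LAC7 (LOC_Os01g63190) had 13 and 2 reads, a ratio of 5.73 (1.30 to 52.3). A miR397 site with score 4 in the protein kinase gene SAPK6 (LOC_Os02g34600) had 22 reads in cadmium and 0 in control. This was 6.47-fold higher against the floor, with an interval from 4.83.

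The main miR408 site, in LOC_Os08g37670, was 4.83-fold higher in cadmium (4.42 to 5.29). Its annotation is a glycine-rich RNA-binding protein of rapeseed, by best match, and no other miR408 locus had over 4 reads at a site. For miR528, the site of LOC_Os07g38290, annotated as a proline-rich receptor-like kinase, had 421 and 122 reads, 3.04-fold higher (2.48 to 3.75). D3 (LOC_Os06g06050), an F-box gene of strigolactone signalling, had 40 and 7 reads, a log2 ratio of 2.33. IAR1 (LOC_Os08g36420), named for resistance to IAA-alanine, had 18 reads and 1 read, a ratio of 15.9 (2.51 to 661). Its 5 isoforms carry the same reads and fill 5 of the 10 largest higher entries. LOC_Os03g03724, without annotation, had 121 reads in cadmium and 0 in control, at a category 2 site with the weakest alignment score allowed, 4. This was 35.6-fold higher against the floor, with an interval from 28.5. LOC_Os01g66170, also without annotation and with score 4, had 17 and 0 reads, 5.00-fold higher against the floor, with an interval from 3.64. At 2 ascorbate oxidase loci miR528 sites had 14 reads in cadmium and 0 in control. The sites of miR528 had a median log2 ratio of 3.99, at percentile 100 of random lists, with the isoforms of IAR1 holding 5 of the 8 sites. By locus the median was 1.97 (percentile 98.5, 4 loci).

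Summed cleavage reads of NF-YA and scarecrow-like transcripts were lower in cadmium, mostly at NFYA9 and at SCL6 of LOC_Os04g46860, and by locus neither family lay outside the range of random lists. Reads of miR169, whose targets encode NF-YA subunits of the CCAAT-box factor, summed to 594 in cadmium and 1103 in control, 2.11-fold lower (1.90 to 2.33). NFYA9 carried most of them, with 487 and 979 reads, a log2 ratio of -1.19, and without this locus the sum was 107 and 124 reads, 1.31-fold lower (1.01 to 1.72). Of 6 abundant miR169 loci with reads in both, 1 was higher in cadmium, NFYA6 (LOC_Os03g07880, 19 and 10 reads). The median of the 16 sites was -0.96 (percentile 0.91), and by locus -0.95 (percentile 10.1). Reads of miR171, which cuts scarecrow-like GRAS factors, summed to 451 and 682, 1.71-fold lower (1.52 to 1.94). SCL6 at LOC_Os04g46860 had 113 and 235 reads at position 1337, a log2 ratio of -1.24, and 11 and 53 reads at position 1334, a log2 ratio of -2.45. SCL6 at LOC_Os06g01620 had 207 and 232 reads at position 467, a log2 ratio of -0.35, and 59 and 113 reads at position 464. SCL6 at LOC_Os10g40390 had 23 and 20 reads, a log2 ratio of 0.02, and SCL6 at LOC_Os02g44370 had 7 reads and 1 read at position 1537. The site median of the family was -0.79 (percentile 10.97), and by locus -0.41 (percentile 17.5).

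Reads of miR172, which cuts APETALA2-like factors of flowering, summed to 560 and 734, 1.49-fold lower (1.33 to 1.66). AP2 at LOC_Os05g03040 had 516 and 676 reads, a log2 ratio of -0.57, and the median of the family was -0.57 (percentile 21.2 by site, 39.1 by locus). Dicer-like 1, the enzyme that makes miRNAs and itself a target of miR162, had 2 reads in cadmium and 14 in control at position 2988 (LOC_Os03g02970), 7.94-fold lower (1.82 to 71.9). The remorin gene LOC_Os04g45070 had 1 read and 17 reads, 19.3-fold lower (3.02 to 805), at a site of miR6253. A miR395 site of the same gene went the other way on few reads. The miR395 sum was 16 and 15 reads with this locus and 10 and 12 without it. LOC_Os08g33820, a chlorophyll a-b binding protein gene, had 1 read and 13 reads at a miR7695 site, a log2 ratio of -3.88.

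Cleavage-site reads of auxin-pathway transcripts differed in both directions. At miR160 sites, the auxin response factor ARF18 had 1262 and 1163 reads, a log2 ratio of -0.06 that turned to 0.19 with the median of shared sites set to 0, ARF22 (LOC_Os10g33940) 366 and 537 reads, -0.73, and ARF8 (LOC_Os02g41800) 125 and 221 reads, -1.01. ARF13 (LOC_Os04g59430) went the other way, with 8 reads in cadmium and 0 in control. This was 2.35-fold higher against the floor, with an interval from 1.51. The family sum was 1786 and 1956 reads, 1.24-fold lower (1.16 to 1.32), and without ARF18 it was 1.71-fold lower (1.53 to 1.92). Its site median was -0.33 (percentile 55.2) and its locus median -0.67 (percentile 13.3). The ARF targets of miR167 had 14 reads in cadmium and 29 in control, 2.35-fold lower (1.20 to 4.81), and ARF17 (LOC_Os06g46410) 8 and 24 of these. Most miR167 reads were at TIC32 (LOC_Os06g03830), annotated as a chloroplast short-chain dehydrogenase, with 579 and 428 reads, and the family sum of 594 and 468 reads had a ratio of 1.12 (0.99 to 1.27). The site median of miR167 was -0.76 (percentile 17.4). Sites of miR393, which cuts transcripts of TIR1-type auxin receptors, summed to 120 and 69 reads, a ratio of 1.53 (1.13 to 2.09). The receptor gene Os05g0150500 (LOC_Os05g05800) had 84 and 33 reads, a log2 ratio of 1.17, and Os04g0395600 (LOC_Os04g32460) had 25 and 22, a log2 ratio of 0.00. Without Os05g0150500 the family had 36 reads in each library, a log2 ratio of -0.18. The median of miR393 was 0.00 by site (percentile 66.6) and by locus (percentile 44.7).

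Reads of NAC factors differed in opposite directions between members, and the MADS factors MADS27 and MADS57 had more reads in cadmium. The miR164 sum was 405 and 273 reads, a ratio of 1.31 (1.12 to 1.53), which was 0.99 (0.81 to 1.20) without NAC021 at LOC_Os12g41680. NAC021 at LOC_Os12g41680 had 183 and 74 reads, a log2 ratio of 1.13, NAC021 at LOC_Os06g46270 had 118 and 74, 0.49, and NAC021 at LOC_Os08g10080 had 45 and 70, -0.82. NAC100 at LOC_Os02g36880 had 30 and 7 reads, a log2 ratio of 1.92, and NAC100 at LOC_Os04g38720 had 8 and 27, -1.94. The site median of miR164 was 1.52 (percentile 98.8), and the locus median 0.49 (percentile 79.8). The miR444 sum was 101 and 43 reads, a ratio of 2.07 (1.44 to 3.03), which was 1.47 (0.94 to 2.34) without MADS27. Its MADS-box targets MADS27 (LOC_Os02g36924) and MADS57 (LOC_Os02g49840) had 46 and 10 reads and 37 and 18 reads, log2 ratios of 2.02 and 0.86. The site and locus medians of miR444 were 0.86 (percentiles 97.1 and 79.6).

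Growth-regulating factor and SPL transcripts were nearly level in sum. Sites of miR396, which cuts growth-regulating factor transcripts, summed to 69 and 61 reads, of which those factors held 66 and 59. The family sum had a ratio of 1.00 (0.70 to 1.43), and without GRF3 1.83 (1.13 to 3.05). Within them GRF3 (LOC_Os04g51190) had 15 and 35 reads, a log2 ratio of -1.40, GRF9 (LOC_Os03g47140) had 17 and 10, 0.58, and GRF1 (LOC_Os02g53690) 11 reads and 1 read, a ratio of 9.70 (1.41 to 418). The miR396 median was 0.21 by site (percentile 68.0) and 0.40 by locus (percentile 70.8). The miR156, miR529 and miR535 family, which cuts squamosa-type (SPL) transcripts, had 88.5 and 76 reads, a ratio of 1.03 (0.74 to 1.41). SPL2 (LOC_Os01g69830) had 19 and 13 reads, a log2 ratio of 0.37. The site median of the family was -1.18 (percentile 1.80), set by isoforms of SPL12 (LOC_Os06g49010), which share 9 and 18 reads. The sum of miR159 and miR319 was 107 and 67.5 reads, a ratio of 1.40 (1.01 to 1.91), and GAMYB (LOC_Os01g59660) had 90 and 54 reads, with a site median of 0.56 (percentile 90.05). Sites of miR166 summed to 152 and 170 reads, 1.27-fold lower (1.01 to 1.59), with a median of -0.32 by site (percentile 45.5) and -0.00 by locus (percentile 44.0). HOX10 (LOC_Os03g01890) had 128 and 148 raw reads but 22.3 and 24.7 normalized reads per transcript, and HOX9 (LOC_Os10g33960) had 126 and 150 raw reads. Together these raw counts exceed the family sum, so most of these reads match both genes. HOX10 and HOX9 are therefore not separate evidence.

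The remaining families had few reads. Sums in cadmium and control were 33 and 34 for miR394, with 33 and 29 at the F-box gene FBX6 (LOC_Os01g69940), and 16 and 15 for miR395, with 5 and 0 at the ATP-sulfurylase gene APS3 (LOC_Os03g53230). Sites of miR1425 had 31 and 18 reads, a ratio of 1.52 (0.82 to 2.88), with 20 and 9 at the fertility restorer-like gene Rf1 (LOC_Os10g35436). Sites of miR827 had 7 and 10 reads, with 5 and 8 at an SPX-domain gene (LOC_Os04g48390), and sites of miR1432 had 8 and 2, with 6 and 0 at the calcium-binding protein gene CML11 (LOC_Os03g59770). Sums were 1.5 and 1 for miR390, 0 and 3 for miR399, 2 and 3 for miR2118, and 0 and 1 for each of miR530 and miR820. The miR390 site in a receptor-like kinase gene (LOC_Os04g45170) and the miR820 site in the DNA methyltransferase gene DRM2 (LOC_Os03g02010) had 1 read each. Of the 19 families with 20 or more summed reads, 5 were over 2-fold higher in cadmium and 1 over 2-fold lower. The lower one, miR169, had a log2 ratio of -0.82 with the median of shared sites set to 0, and miR444 had 0.75 when scaled by summed site reads, so neither passed 2-fold there. The direction of 5 families, miR156 with miR529 and miR535, miR167, miR394, miR395 and miR396, depended on the scaling.

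**Figure D2:**
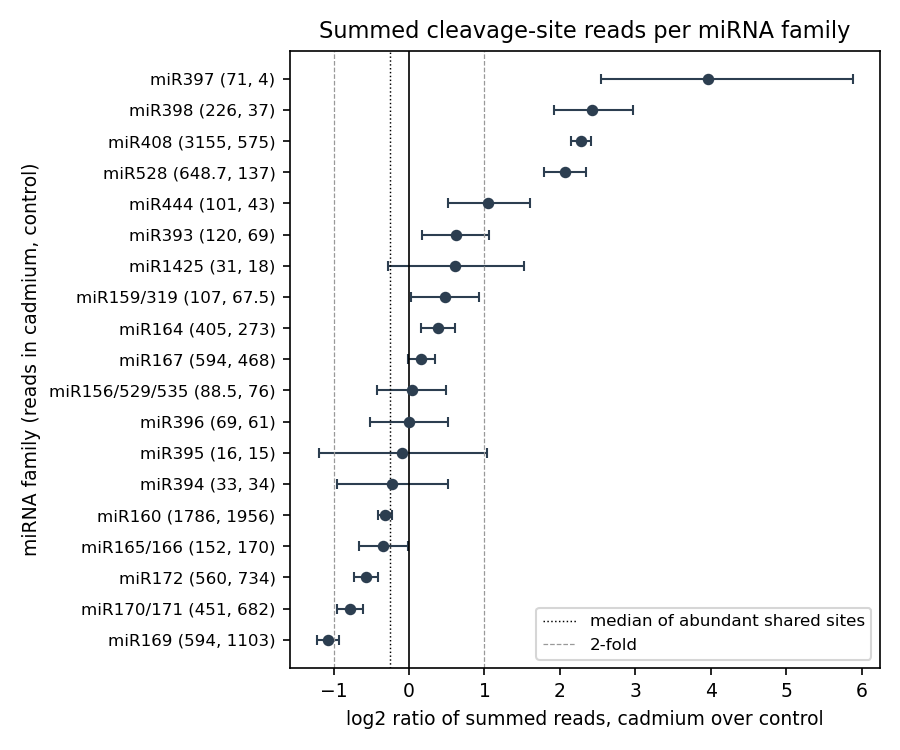
Log2 ratio of summed normalized cleavage-site reads, cadmium over control, for 19 miRNA families with 20 or more reads, 1 library per treatment. Points are ratios per library read, bars 95% counting intervals, the numbers beside each name are reads in cadmium and control, the dashed lines mark 2-fold and the dotted line is the median of abundant shared sites (-0.26); miR397, miR398, miR408 and miR528 lie highest and miR169 lowest.

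By target function, cleavage-site reads of transcription factor transcripts were lower and those of laccase and redox enzyme transcripts higher in the cadmium library. Transcription factors, 163 sites on 65 loci, had 4241 and 5123 normalized reads, 1.37-fold lower (1.31 to 1.43). Their median log2 ratio was -0.51 by site, below the 95% range of random lists (-0.39 to -0.03), and -0.39 by locus (percentile 1.27). With the median of shared sites set to 0 the site median was -0.26. Of their 36 abundant loci with reads in both, 4 were at least 2-fold higher and 8 at least 2-fold lower. The random lists also drew on the 8 high loci of miR397, miR398, miR408 and miR528. The 47 abundant loci outside those families had a median of -0.31, and all sites outside them were 1.28-fold lower. The transcription factor values were close to these. The copper protein list, whose words left out SODCC2, had 63 and 4 reads, a ratio of 13.9 (5.17 to 52.6). With SODCC2, the sites annotated as copper proteins had the 265 and 39 reads given above, a ratio of 5.99 (4.27 to 8.62). The cell wall and lignin list, with laccases in it, had 49 and 4 reads, 10.8-fold higher (3.96 to 41.2). Redox enzymes had 220 and 35 reads, a ratio of 5.54 (3.87 to 8.16), of which SODCC2 held 202 and 35. The protein kinase list, matched on annotation words, had 474.5 and 153.6 reads, 2.73-fold higher (2.26 to 3.28). Most came from the miR528 site of LOC_Os07g38290, whose kinase name is a best match to an Arabidopsis protein and may not describe the rice gene.

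Auxin signalling had 1910 and 2042 reads, 1.21-fold lower (1.14 to 1.29), with a median of -0.06 by site (percentile 82.0), 0.19 with the median of shared sites set to 0, and -0.60 by locus (percentile 9.89). Photosynthesis and chloroplast had 596.5 and 469 reads, a ratio of 1.12 (0.99 to 1.27) and a site median of 0.25 (percentile 80.8), most of them at TIC32. The F-box and ubiquitin list had 89 and 51.8 reads, a ratio of 1.52 (1.06 to 2.17), with a median of 0.01 by site (percentile 71.5) and by locus (percentile 49.2). The miR528 site of D3 held 40 and 7 of these reads and FBX6 33 and 29, so the higher sum came mostly from D3. Small RNA machinery was the DCL1 site alone. The sulfur and thiol list had 11 and 4 reads, transporters 4 and 2, chaperones 0 and 2, ribosome and translation 6 and 5, disease resistance 1 and 0, and pentatricopeptide repeat proteins 0 and 1. No site annotation matched the words of the metal transport list, which would miss a metal transporter gene annotated under another name. Of the 17 lists with enough sites for a median, 5 lay outside the middle 95% of random lists by site, namely miR156 with miR529 and miR535, miR164, miR169, miR528 and transcription factors. By locus 2 of 13 did, miR528 and transcription factors.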

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

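All alternatives here were chosen before the data were examined, except those for family sums, which were chosen after the results were seen. No paired analysis was possible because each treatment has 1 library. Sites of category 0 to 2 in at least 1 library had category 0 shares of 42.4% in cadmium and 33.6% in control. Sites with a deposited site p-value at or below 0.05 numbered 138 in cadmium, 122 in control and 118 in both, with category 0 shares of 80.4% and 73.0%. An alignment score at or below 3 left 191 and 183 sites, category 0 shares of 46.1% and 42.1%, and 14 sites over 2-fold higher and 22 lower. Counting miRNA-site pairs gave 966, 1009 and 740 pairs, shares of 49.8% and 43.6%, and 50 pairs higher and 116 lower, since family members repeat the same reads. With 1 site per locus there were 210 in cadmium, 217 in control and 112 in both, with 14 higher and 11 lower. Setting the median of shared sites to 0 gave 26 sites higher and 12 lower, and a pseudocount of 1 read with absent sites included gave 27 higher and 20 lower. With no read minimum 39 sites were higher and 49 lower, and with a minimum of 50 reads 5 and 9. The 2 other scalings were the alternatives run for named sites. They subtract a constant of -0.26 or 0.30 from every log2 ratio, so no named site past 2-fold could change sign. No family sum past 2-fold, and no list outside the random range, changed sign in the alternatives that gave it a value. Over all values of each kind, 64 of the named-site values stayed within their intervals and 16 moved, as did 66 and 24 for family sums, 109 and 9 for family lists and 31 and 3 for target lists. Without its locus with the most reads, the sum of miR164 had a log2 ratio of -0.02, that of miR393 -0.18, that of miR167 -1.60 and that of miR396 0.87. An alignment score at or below 3 moved the log2 ratio of miR395 to 2.14 and gave none for miR167. Depth is a limit, since 107 sites in cadmium and 149 in control rest on 1 read.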

Other observations

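All tests in this part were chosen after the data were seen, and that of the deposited p-values with equal library totals before its own result was computed.

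Adjacent cleavage positions were compared in the SCL6 transcripts, where miR171 family members cut at positions 3 nt apart. At LOC_Os06g01620 the upstream position (464, against 467) held 59 of 266 reads in cadmium (22.2%, 95% interval 17.3 to 27.7) and 113 of 345 in control (32.8%, 27.8 to 38.0). At LOC_Os04g46860 (1334 against 1337) it held 11 of 124 reads (8.87%, 4.51 to 15.3) and 53 of 288 (18.4%, 14.1 to 23.4). LOC_Os02g44360 had the upstream share higher in cadmium, 5 of 23 reads against 1 of 23, and LOC_Os10g40390 had 23 of 23 against 20 of 22. At LOC_Os02g44370 the upstream position had 0 of 7 reads and 2 of 3. These shares compare 2 libraries, and their intervals do not cover PCR duplication.

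Predicted copper-protein targets were often without any read. For miR397, 9 laccase loci were predicted and had no reads in either library, beside 6 with reads, and for miR408, 7 loci annotated as chemocyanin, blue copper protein or laccase had none, beside 1 with a single read. The small RNA candidates without a miRNA family number had 17 sites, with 17 reads in cadmium and 4 in control.

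Targets of miR397, miR398, miR408 and miR528 had more cleavage reads in cadmium at all 12 of their loci with 10 or more reads, of which 5 have alignment scores at or below 3. A library depth or scaling error would move all loci alike. The 47 other abundant loci with reads in both had a median log2 ratio of -0.31 (quartiles -0.95 and 0.43). The 8 loci of these families had 2.34 (range 1.01 to 3.99). These families were grouped after their values were seen, so a gap between the groups was built in. The values show only that no single scaling factor would level both groups. A single dominant site is argued against by a ratio of 4.72 (4.02 to 5.57) without the miR408 site of LOC_Os08g37670. Weak predictions are argued against by a ratio of 3.67 (3.09 to 4.39) over sites with alignment scores at or below 3, also without that site (4.58 with it). The sum behind 3.67 was 670 reads in cadmium and 161 in control. Most of them were at LOC_Os07g38290 (421 and 122) and SODCC2 (202 and 35), so this ratio rests mainly on these loci. More of the target transcripts, rather than more cutting, cannot be told apart from a change in cleavage, because the table has 0 columns of transcript levels. An effect of cadmium on cleavage stays open as an untested hypothesis, since with 1 library per treatment the treatment and the library cannot be told apart.

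Most deposited Fisher p-values are small even where reads are few: 497 of 539 sites (92.2%) have a deposited p at or below 0.05, among them all 193 sites with a single read in the 2 libraries together. Fisher's exact test on raw reads against library totals, which compares these 2 libraries and not the treatments, gave 100 sites at or below 0.05 and 56 sites on 32 loci after Benjamini-Hochberg adjustment, 25 higher and 31 lower in cadmium. The first explanation tested, depth-scaled values entered as counts against equal totals of 1e+09 reads, is argued against, since it returned 5.01% of the deposited values. With unequal totals, in the share of 0.459 for cadmium that the cadmium-only sites imply, the rounded depth-scaled values returned 96.1% of the deposited p-values at the other 389 sites (log10 within 0.05 or 0.1%), so depth-scaled values entered as counts may be the source. That share is not the 0.531 of the library reads that cadmium has, and where it comes from was not found; no biological explanation was tested.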
